A study of Homo sapiens with 6 samples.

How the data were processed

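Poly(A) RNA was measured in 6 libraries labelled as HTR-8/SVneo cells, 3 transfected with an empty plasmid and 3 with a plasmid for the long noncoding RNA lnc-SLC4A1-1. The line is that of the series title and sample characteristics, but the descriptions of overexpression replicates 2 and 3 name it HTR-9 and HTR-10 instead. These were taken as typing errors, which was not tested. Groups and replicate numbers were taken from the sample titles. Library columns were matched through the sample descriptions, whose own numbers differ from those of the titles. In both groups the numbers in the descriptions start at 2. Whether a library with a lower number existed was not tested. The labels do not say whether the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical. The labels disagree on the Illumina instrument model, and no strand setting is given.

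The authors deposited 1 table of RPKM values (reads per kilobase of gene length and per 1000000 reads assigned to genes) with 45817 gene records and 6 library columns. TopHat is named as aligner and hg19 as genome build, per the submitters' processing notes, and the TopHat version, the counting tool and the gene annotation are not given in the sources used here. The table gives the gene type, position, strand and length of each record. Of 18292 protein-coding records whose symbol was found in the GENCODE annotation for GRCh37, 99.9% overlapped the annotated gene of that symbol, and coordinates are given on hg19 as the table lists them. Multiplied by gene length, the deposited RPKM values sum to 1000000 in every library and come in steps of the size of 1 read. Reads per gene and depth were computed from these steps, and 99.8% of values above 0 in every library lay within 0.05 of a whole read. The depth was between 25173173 and 29526926 reads in genes. Records with 2 reads were about as frequent as records with 1 read, and the labels do not say whether the mates of a pair were counted separately, so counting error can be larger than the read numbers imply. Limits set by a count of 0 assume 3 reads and cover counting error only.

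A count test had been fixed for the case that the table held raw counts, together with a fallback for normalized values. The table held RPKM, so the fallback was used. Genes with a mean of at least 1 RPKM over the 6 libraries were kept, which left 14067 genes. Values were transformed as log2(RPKM + 1) and fitted by group with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all genes tested, and the threshold was an adjusted p of 0.05. Fold changes on the log2(RPKM + 1) scale understate the change of genes with low values. Tables were read with Python 3.11.15, pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.

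Before the data were examined, 32 gene lists were fixed (831 entries, of which 818 matched a record by symbol or Entrez identifier). Lists with at least 5 tested members, 28 in all, were tested with camera at a preset correlation between genes of 0.01, with adjustment over lists. Camera with an estimated correlation and fry were run beside it. Fry asks whether the members of a list move on balance in 1 direction and does not compare them with other genes. Endothelial markers had 4 tested members, leukocyte markers 1 and erythroid markers 1, and these lists were not tested. None of the mitochondrially encoded protein genes matched a record, and their list was not analysed here.

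The genes named in the text followed a rule fixed before the data were examined. SLC4A1, any record for the lncRNA, CXCL8, IL1B, TNF, IL6 and CXCL1 were named whatever their values. The cytokine genes among them were chosen because the study was known to follow CXCL8 and NF-kB linked cytokines for this lncRNA. Their choice is therefore not independent of that study. Among genes past the threshold with at least 2 RPKM in the higher group and no overlap between the groups, the 10 with the largest rise and the 10 with the largest fall were named, and with fewer than 5 in a direction the 5 with the smallest p. Up to 4 members past the threshold were named from every list, or the member with the smallest p. XIST and genes on the Y chromosome were left out. Genes named only because they passed after adjustment over the list alone were chosen after their values were seen.

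The test was tried on data simulated for this comparison, with known changes in 200 genes and a further list of 30 raised 1.5-fold, and 13953 genes passed the filter. At the adjusted threshold limma recovered 11.9% of 67 genes changed 1.5-fold, 56.7% of 67 changed 2-fold and 90.9% of 66 changed 4-fold, and of 114 calls, which include members of the raised list, 4 fell on unchanged genes. With the GC and length trend of every library removed, an alternative described below, 13 of 175 calls fell on unchanged genes. The raised list was called by camera, and 0 of 30 unchanged lists were. The simulated lists held genes drawn at random with independent counts. They therefore do not show how often camera calls unchanged lists whose genes vary together. For single genes, the simulation carried the GC and length trends estimated by the same regression that the alternative removes. Genes of similar level were given the same spread beyond counting error. Rates of recovery and of calls on unchanged genes can therefore differ in the real data.

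The alternatives were limma-voom on the computed reads, log2(RPKM + 0.1), no filter except a value above 0, a mean of at least 5 RPKM, the replicate number as a block, and leaving out every library in turn. Added after the data were seen were scaling by median-of-ratios factors, removal of the trend of every library with GC content and log length by local regression (span 0.3, for 13490 genes with a GC value, 95.9% of those tested), leaving out control replicate 1 and overexpression replicate 3 together, and protein-coding records alone. Control replicate 1 and overexpression replicate 3 were chosen because they lay at the ends of the first principal component. The spread of the remaining libraries can therefore be too small, and the p-values of that fit too low. GC content was taken from the longest GENCODE transcript of a gene. Estimated library weights were tried and not used, since the estimate did not converge.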

Results

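Poly(A) RNA was sequenced from HTR-8/SVneo, a human trophoblast line from early placenta immortalised with SV40 large T antigen. In 3 control libraries the cells had received an empty plasmid, and in 3 overexpression libraries a plasmid for the long noncoding RNA (lncRNA) lnc-SLC4A1-1. Reads in genes, computed from the RPKM steps, numbered 25173173, 27904414 and 25356864 in control replicates 1 to 3 and 25469113, 29526926 and 28550535 in overexpression replicates 1 to 3. Over 14067 genes, Pearson correlations across genes lay between 0.961 and 0.993 for library pairs within groups and between 0.939 and 0.986 for pairs between groups. The first principal component of log2(RPKM + 1) held 61.4% of the variance and placed control replicate 1 at -45.8 and overexpression replicate 3 at 33.0, with the other libraries from -6.72 to 10.9. The next component held 20.05% and separated the groups, with controls from -21.7 to 2.67 and overexpression libraries from 9.08 to 14.5.

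**Figure D1:**
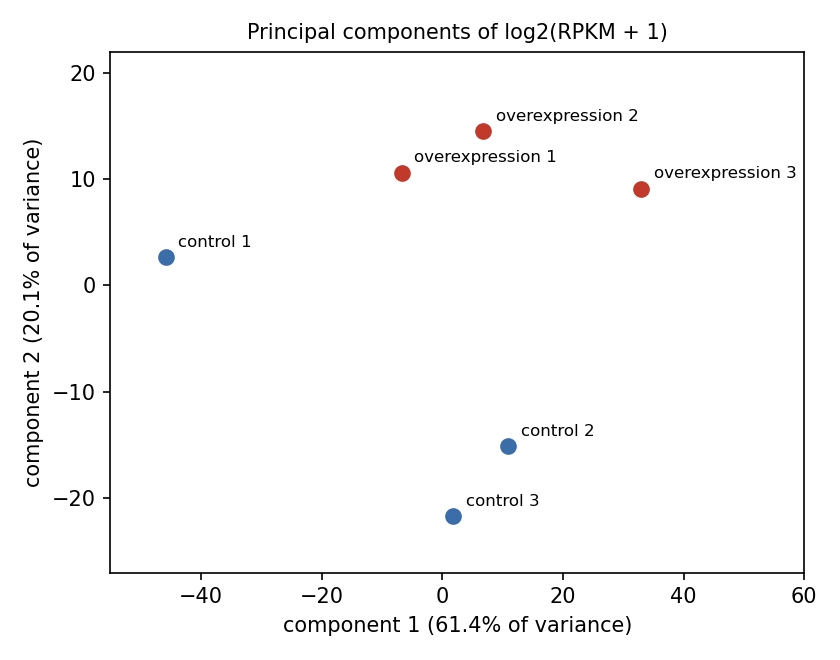
Scores of the 6 libraries on the first principal component (x axis, 61.4% of variance) and the next one (y axis, 20.05%) of log2(RPKM + 1), controls in blue and overexpression libraries in red. Control replicate 1 (-45.8) and overexpression replicate 3 (33.0) lie at the ends of the x axis, and the groups part on the y axis.

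SLC4A1, whose symbol is part of the name of the lncRNA, was examined first. It is not a direct check of the labels, since the lncRNA has no record under its own name. SLC4A1, which encodes the band 3 anion exchanger of red blood cells, rose from 0.034 ± 0.046 RPKM in controls to 18.9 ± 2.25 RPKM with overexpression (SD, n = 3 and 3). The change was 4.26 ± 0.14 (SE) on the log2(RPKM + 1) scale, with an adjusted p of 1.6e-05 in limma. The 3 controls held 14 reads over this record together, 12 of them in control replicate 2, and the overexpression libraries held 2124 to 3011 reads each. The ratio of the mean RPKM values was 552 and rests on those 14 control reads. The record spans positions 42325758 to 42345502 on the minus strand of chromosome 17 with a gene length of 4953 bases, and SLC4A1 is the only GENCODE gene overlapping it. No record of the table carries the name of the lncRNA, which was therefore not analysed here under its own name.

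No other gene around SLC4A1 on chromosome 17 passed the threshold. Of 21 tested genes in the list fixed for this region, SLC4A1 was the 1 that rose, over all genes and adjusted over the list alone. The other 20 had log2 fold changes from -0.36 to 0.45, with a median of 0.05. Camera gave the list, SLC4A1 included, an adjusted p of 0.13, and 0.0296 without control replicate 3, and fry gave it 0.0344.

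CXCL8, which encodes the neutrophil-attracting chemokine interleukin 8, rose in every overexpression library. It went from 15.1 ± 2.09 to 61.5 ± 3.83 RPKM (SD, n = 3 and 3), a log2 change of 1.96 ± 0.13 (SE, adjusted p = 0.00122 in limma) and a ratio of means of 4.07. The gene lies on chromosome 4 at 74606223 to 74609433. CXCL3, a related chemokine gene on the same chromosome (74902306 to 74904490), rose from 2.19 ± 0.458 to 6.20 ± 0.51 RPKM, by 1.18 ± 0.15 on the log2 scale (adjusted p = 0.0374). Among the 6 fits that left out a library, the CXCL3 call held only without control replicate 1, with an adjusted p of 0.0877 to 0.182 in the others. With limma-voom it had 0.0541 and without the filter 0.154.

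The other cytokine genes fixed beforehand did not pass the threshold. IL1B, encoding the inflammatory cytokine interleukin 1 beta, was at 57.6 ± 11 and 61.6 ± 6.90 RPKM (log2 change 0.11 ± 0.16, adjusted p = 0.792). IL6 was at 1.67 ± 0.55 and 1.74 ± 0.106 RPKM (0.06 ± 0.18, adjusted p = 0.902). The chemokine gene CXCL1 was at 7.21 ± 0.71 and 10.5 ± 0.753 RPKM (0.49 ± 0.13, adjusted p = 0.293). TNF was listed at 0 in all 6 libraries, which allows up to 0.0606 to 0.0711 RPKM by the 3-read limit of each library.

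As a group, 12 inflammatory cytokine and chemokine genes were tested, and 2 rose (CXCL8 and CXCL3), none fell and 10 did not pass. Adjusted over the list alone, 7 rose, adding IL11, LIF, IL32, CXCL1 and CXCL2. IL11, a cytokine gene of the interleukin 6 family, was at 49.9 ± 6.50 and 87.4 ± 6.67 RPKM. The list was higher in camera (median log2 change 0.52, adjusted p = 2.37e-06), with adjusted p = 0.235 with an estimated correlation. Among 25 genes of the NF-kB pathway and its feedback, 0 passed over all genes and 3 rose when adjusted over the list alone. These were TNFAIP3, TNIP2, both negative regulators of NF-kB signalling, and RELB, an NF-kB subunit. TNFAIP3 was at 2.75 ± 0.392 and 5.07 ± 0.415 RPKM (0.70 ± 0.14, adjusted p = 0.172 over all genes). It passed with GC and length trends removed (0.0075) and without control replicate 1 and overexpression replicate 3 together (0.0375). The NF-kB list was higher in camera (median 0.22, adjusted p = 0.00148), with adjusted p = 0.238 with an estimated correlation.

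**Figure D2:**
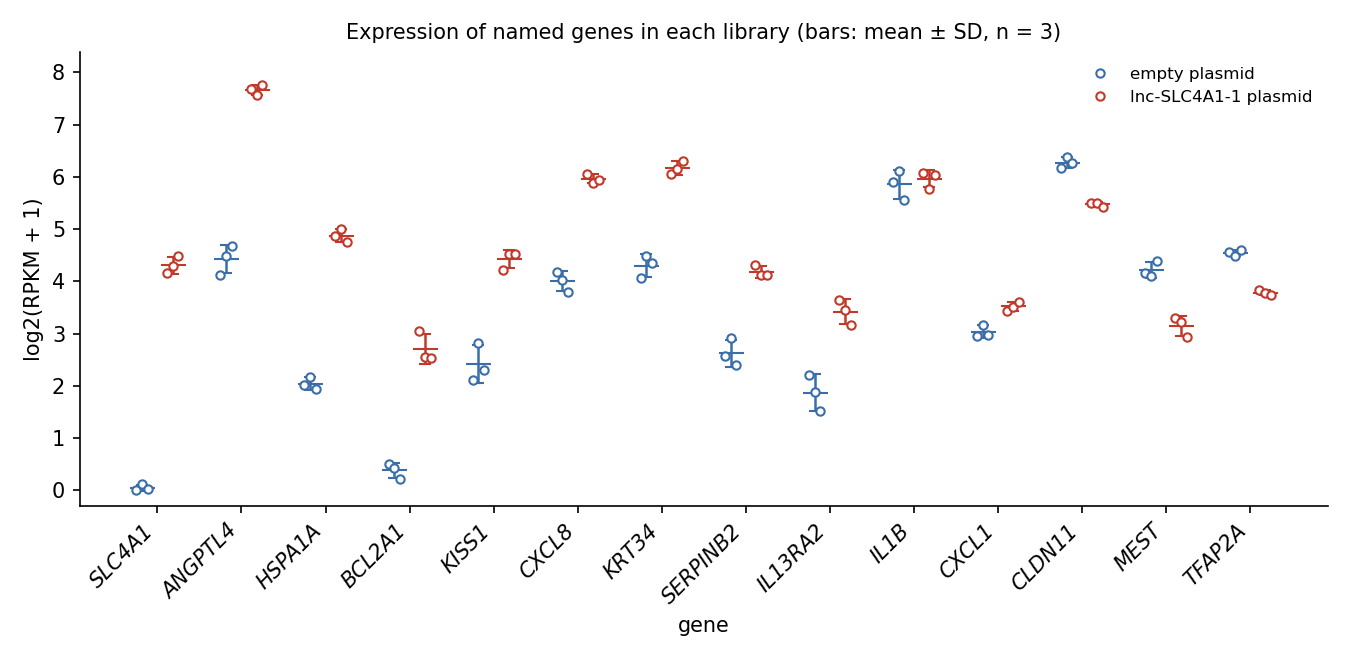
Level of 14 named genes as log2(RPKM + 1) on the y axis in each library, controls in blue and overexpression libraries in red. Circles are libraries, and the bars give mean and SD over 3 libraries. SLC4A1, ANGPTL4, HSPA1A, BCL2A1, KISS1, CXCL8, KRT34, SERPINB2 and IL13RA2 were higher, CLDN11, MEST and TFAP2A were lower, and IL1B and CXCL1 did not pass the threshold.

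On the log2(RPKM + 1) scale the largest rise among called genes after SLC4A1 was that of ANGPTL4, which encodes a secreted inhibitor of lipoprotein lipase. ANGPTL4 (chromosome 19, 8429011 to 8439259) rose from 20.8 ± 4.0 to 202 ± 13.4 RPKM, by 3.24 ± 0.15 on the log2 scale (adjusted p = 1.1e-04, limma). HSPA1A (chromosome 6, 31783291 to 31785719), a gene of the inducible heat shock protein 70, rose from 3.13 ± 0.354 to 28.4 ± 2.48 RPKM (2.83 ± 0.13, adjusted p = 1.1e-04). BCL2A1 (chromosome 15, 80253232 to 80263643), which encodes an antiapoptotic relative of BCL2, rose from 0.31 ± 0.13 to 5.64 ± 1.39 RPKM (2.33 ± 0.18, adjusted p = 0.00248). Its ratio of mean RPKM values, 18.2, was above that of ANGPTL4, 9.73. The falls were smaller, and the transcription factor gene TFAP2A, active in trophoblast, was among them.

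Among 14067 genes, 28 passed an adjusted p of 0.05 in limma, of which 24 rose and 4 fell, and 24 changed by at least 1 on the log2 scale. At an unadjusted p of 0.05, 1701 genes passed. In all 28 the 3 values of 1 group lay outside those of the other, a separation seen in 19.2% of all tested genes and expected by chance in 10%. Of these 28 records 9 overlap another record of the table, with which they can share reads. The call count was 34 without control replicate 1, 21 without control replicate 2, 10 without control replicate 3, and 12, 7 and 14 without overexpression replicates 1, 2 and 3. With the trends with GC content and gene length removed it was 117 (82 higher, 35 lower), and without control replicate 1 and overexpression replicate 3 together it was 419 (359 higher, 60 lower).

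The remaining genes of the largest rises had diverse roles. KISS1, the gene of the peptide kisspeptin made by placental trophoblast, rose from 4.44 ± 1.44 to 20.6 ± 2.53 RPKM (2.01 ± 0.20, adjusted p = 0.00749). KRT34, a hair keratin gene, rose from 18.9 ± 2.88 to 71.4 ± 6.57 RPKM (1.87 ± 0.14, adjusted p = 0.00248). HSPA1B, the near-identical copy of HSPA1A, rose from 75.2 ± 15.8 to 260.0 ± 34.2 RPKM (1.79 ± 0.17, adjusted p = 0.00749), and how reads were split between the copies is uncertain. SERPINB2, encoding plasminogen activator inhibitor type 2, rose from 5.24 ± 1.14 to 17.2 ± 1.46 RPKM (1.56 ± 0.16, adjusted p = 0.00882). IL13RA2, encoding a decoy receptor of interleukin 13, rose from 2.73 ± 0.89 to 9.81 ± 1.73 RPKM (1.55 ± 0.21, adjusted p = 0.0398). SLC4A1, ANGPTL4, HSPA1A, CXCL8, KRT34 and BCL2A1 passed in all 6 fits that left out a library. HSPA1B had an adjusted p of 0.0501 without overexpression replicate 2, and KISS1 0.0941 without control replicate 3 and 0.0563 without overexpression replicate 2. SERPINB2 passed in 3 of the 6 fits and had 0.0720 without control replicate 3, 0.0746 without overexpression replicate 1 and 0.0594 without overexpression replicate 2. IL13RA2 passed only without control replicate 1, with an adjusted p of 0.0755 to 0.204 without the other libraries, and had 0.0531 with limma-voom. Without the filter the calls of HSPA1B (0.0761), KISS1 (0.0802), SERPINB2 (0.0743) and IL13RA2 (0.193) were lost.

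The 4 falls were smaller. CLDN11 (chromosome 3, 170136653 to 170152479), a tight junction gene, fell from 76.2 ± 5.71 to 43.5 ± 1.27 RPKM (-0.79 ± 0.11, adjusted p = 0.0445). MEST (chromosome 7, 130126016 to 130146138), an imprinted gene expressed in placenta, fell from 17.6 ± 1.99 to 7.95 ± 1.14 RPKM (-1.06 ± 0.15, adjusted p = 0.0445). TFAP2A (chromosome 6, 10396916 to 10419797) fell from 22.4 ± 0.898 to 12.8 ± 0.48 RPKM (-0.77 ± 0.11, adjusted p = 0.0488). TRNW, the mitochondrial tryptophan tRNA gene, fell from 61.2 ± 8.32 to 29.3 ± 3.49 RPKM over a record of 68 bases (-1.04 ± 0.14, adjusted p = 0.0445). TRND, the mitochondrial aspartate tRNA gene, was at 39.1 ± 7.24 and 17.3 ± 2.05 RPKM and did not pass (-1.12 ± 0.16, adjusted p = 0.0529). MEST and TFAP2A overlap records on the opposite strand, among them COPG2 and TFAP2A-AS1, and without a stated strand setting their reads cannot be told apart. Each of the 4 passed only without control replicate 1 among the fits that left out a library, and the highest adjusted p was 0.254 (MEST) and 0.240 (TRNW) without control replicate 3, and 0.327 (CLDN11) and 0.412 (TFAP2A) without overexpression replicate 2. With all 6 libraries kept, limma-voom called none of the 4, with an adjusted p of 0.0561 (CLDN11), 0.0531 (MEST), 0.0541 (TFAP2A) and 0.178 (TRNW). Without the filter none of the 4 passed either, at 0.0910, 0.149, 0.0854 and 0.154 in the same order. TRND passed with a mean of at least 5 RPKM (0.0255) and without control replicate 1 and overexpression replicate 3 together (0.0205).

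A few genes of hypoxia and glycolysis rose. Of 26 tested, 3 rose, none fell and 23 did not pass, and 22 had a positive log2 change. ANGPTL4 led, followed by NDRG1, a stress-responsive gene (55.2 ± 5.48 to 148 ± 20.4 RPKM, 1.40 ± 0.14, adjusted p = 0.00749), and CA9, the carbonic anhydrase gene used as a hypoxia marker (5.05 ± 0.60 to 12.1 ± 0.938 RPKM, 1.12 ± 0.13, adjusted p = 0.0240). Adjusted over the list alone, 11 rose, adding among others VEGFA, the vascular growth factor gene (11.2 ± 0.953 to 16.2 ± 1.03 RPKM), and SLC2A1, the glucose transporter gene (39.0 ± 6.85 to 53.5 ± 4.11 RPKM). The list was higher in camera (median 0.33, adjusted p = 1.13e-09), with adjusted p = 0.227 with an estimated correlation. The NDRG1 call was lost without control replicate 3 (0.0592) or overexpression replicate 2 (0.0547). The CA9 call was lost without control replicate 3 (0.171) or any overexpression replicate (0.0775 to 0.204). Without the filter both were lost (0.0624 for NDRG1 and 0.0887 for CA9).

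Heat shock, NRF2 target and immediate early genes were higher as lists, with few members past the threshold. Of 14 heat shock genes 2 rose (HSPA1A and HSPA1B), and 5 did when adjusted over the list alone, adding DNAJB1, a co-chaperone gene (120.1 ± 16.7 to 199.7 ± 10.7 RPKM), HSPE1 and BAG3. Of 19 antioxidant and NRF2 target genes 1 rose, OSGIN1, an oxidative stress induced growth inhibitor (2.94 ± 0.201 to 7.55 ± 0.962 RPKM, 1.11 ± 0.14, adjusted p = 0.0286), and 7 did when adjusted over the list alone. Of 21 immediate early genes 1 rose, DUSP1, the gene of a phosphatase of MAP kinases (149.7 ± 16 to 310.6 ± 22.5 RPKM, 1.05 ± 0.13, adjusted p = 0.0240). Adjusted over the list alone, 8 immediate early genes rose, JUN and JUNB among them, and EGR1 fell (41.1 ± 5.56 to 26.7 ± 2.77 RPKM). Camera gave adjusted p-values of 3.21e-05 for heat shock (median 0.28), 8.42e-06 for NRF2 targets (median 0.30) and 1.38e-05 for immediate early genes (median 0.24). These became adjusted p = 0.227, 0.238 and 0.238 with an estimated correlation. The DUSP1 call held without control replicate 1 or 2 and was lost without any of the other 4 libraries (0.137 to 0.173), and that of OSGIN1 held only without control replicate 1 (0.0826 to 0.171 without the other libraries). Without the filter both were lost (0.108 for DUSP1 and 0.125 for OSGIN1).

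Genes of matrix proteases, their inhibitors and invasion moved both ways. Of 24 tested, 1 rose (SERPINB2) and 23 did not pass, and adjusted over the list alone 7 rose and 2 fell. The risers included MMP1, an interstitial collagenase gene (2.94 ± 0.857 to 7.13 ± 0.575 RPKM), and PLAUR, the urokinase receptor gene (33.7 ± 4.79 to 56.4 ± 0.639 RPKM). Inhibitor genes went both ways. SERPINB2, TIMP1 (97.4 ± 15.9 to 158.9 ± 7.52 RPKM) and SERPINE1 rose, and the fallers were TIMP3 and SERPINE2. None of 24 p53 target genes passed over all genes, and 3 rose when adjusted over the list alone, namely the growth arrest gene GADD45A (85.1 ± 5.41 to 145.9 ± 8.71 RPKM, 0.77 ± 0.11, adjusted p = 0.0529 over all genes), the cell cycle inhibitor gene CDKN1A (88.9 ± 14.4 to 174 ± 18.3 RPKM) and PHLDA3. GADD45A passed over all genes without control replicate 1 (0.0497), with a mean of at least 5 RPKM (0.0367), among protein-coding genes (0.0387), with GC and length trends removed (0.0132) and without control replicate 1 and overexpression replicate 3 together (0.0196). None of 16 genes responsive to TGF-beta and BMP passed over all genes, and 6 rose when adjusted over the list alone, led by the secreted growth factor gene GDF15 (0.95 ± 0.19 on the log2 scale, adjusted p = 0.174 over all genes) and SERPINE1. Camera gave adjusted p-values of 0.00154 (median 0.18), 0.00347 (median 0.13) and 0.0112 (median 0.12) for the 3 lists, which became adjusted p = 0.238, 0.227 and 0.238 with an estimated correlation. Without control replicate 1 and overexpression replicate 3 together, the TGF-beta and BMP list had an adjusted p of 0.116.

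Genes of cell division and of cholesterol synthesis were lower as lists. None of 30 G2 and mitosis genes, none of 30 S phase genes and none of 24 cholesterol synthesis genes passed over all genes. Adjusted over the list alone, SCD of the cholesterol list, encoding a fatty acid desaturase, fell (241.3 ± 21.9 to 144.3 ± 16.8 RPKM, -0.74 ± 0.13, adjusted p = 0.110 over all genes), and no member of the other lists passed. The mitotic kinesin gene KIF20A was at 24.8 ± 2.75 and 14.7 ± 2.88 RPKM (-0.73 ± 0.17, adjusted p = 0.221), and MCM3, of the replicative helicase, at 86.5 ± 7.51 and 64.9 ± 1.36 RPKM (-0.41 ± 0.11, adjusted p = 0.303). MCM3 passed with GC and length trends removed (0.0415), and SCD without control replicate 1 and overexpression replicate 3 together (0.0290). Camera gave adjusted p-values of 6.14e-05 for G2 and mitosis (median -0.22), 0.00172 for S phase (median -0.13) and 0.0123 for cholesterol synthesis (median -0.13), and each became adjusted p = 0.238 with an estimated correlation. Control replicate 1, the library at the low end of the first component, had G2 and mitosis genes at a median of 0.31 (log2) above the other controls. The same median was -0.08 for all genes and 0.113 at the middle of random lists matched on GC content and length. Without control replicate 1 and overexpression replicate 3 together, the G2 and mitosis list had an adjusted p of 0.513, and with fry it had 0.211. The cholesterol list had 0.0708 without control replicate 3 and 0.0782 without overexpression replicate 1.

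Ribosomal protein and respiratory chain genes were higher as lists by small amounts. Of 76 cytoplasmic ribosomal protein genes 74 had a positive log2 change (median 0.18) and of 34 nuclear oxidative phosphorylation genes 28 did (median 0.18), and none passed over all genes or adjusted over the list alone. RPS23 had the smallest p of the ribosomal list (126.6 ± 6.59 and 169.1 ± 11.9 RPKM, 0.41 ± 0.11, adjusted p = 0.299) and NDUFB3, of respiratory complex I, that of the other list (54.4 ± 2.60 and 71.9 ± 2.55 RPKM, 0.40 ± 0.10, adjusted p = 0.293). Camera gave 2.37e-06 and 0.0021, which became adjusted p = 0.602 and 0.604 with an estimated correlation. Without control replicate 1 and overexpression replicate 3 together, the libraries at the ends of the first component, their adjusted p was 0.513 and 0.946, and with fry it was 0.326 for both. The oxidative phosphorylation list had an adjusted p of 0.174 without control replicate 1 alone.

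**Figure D3:**
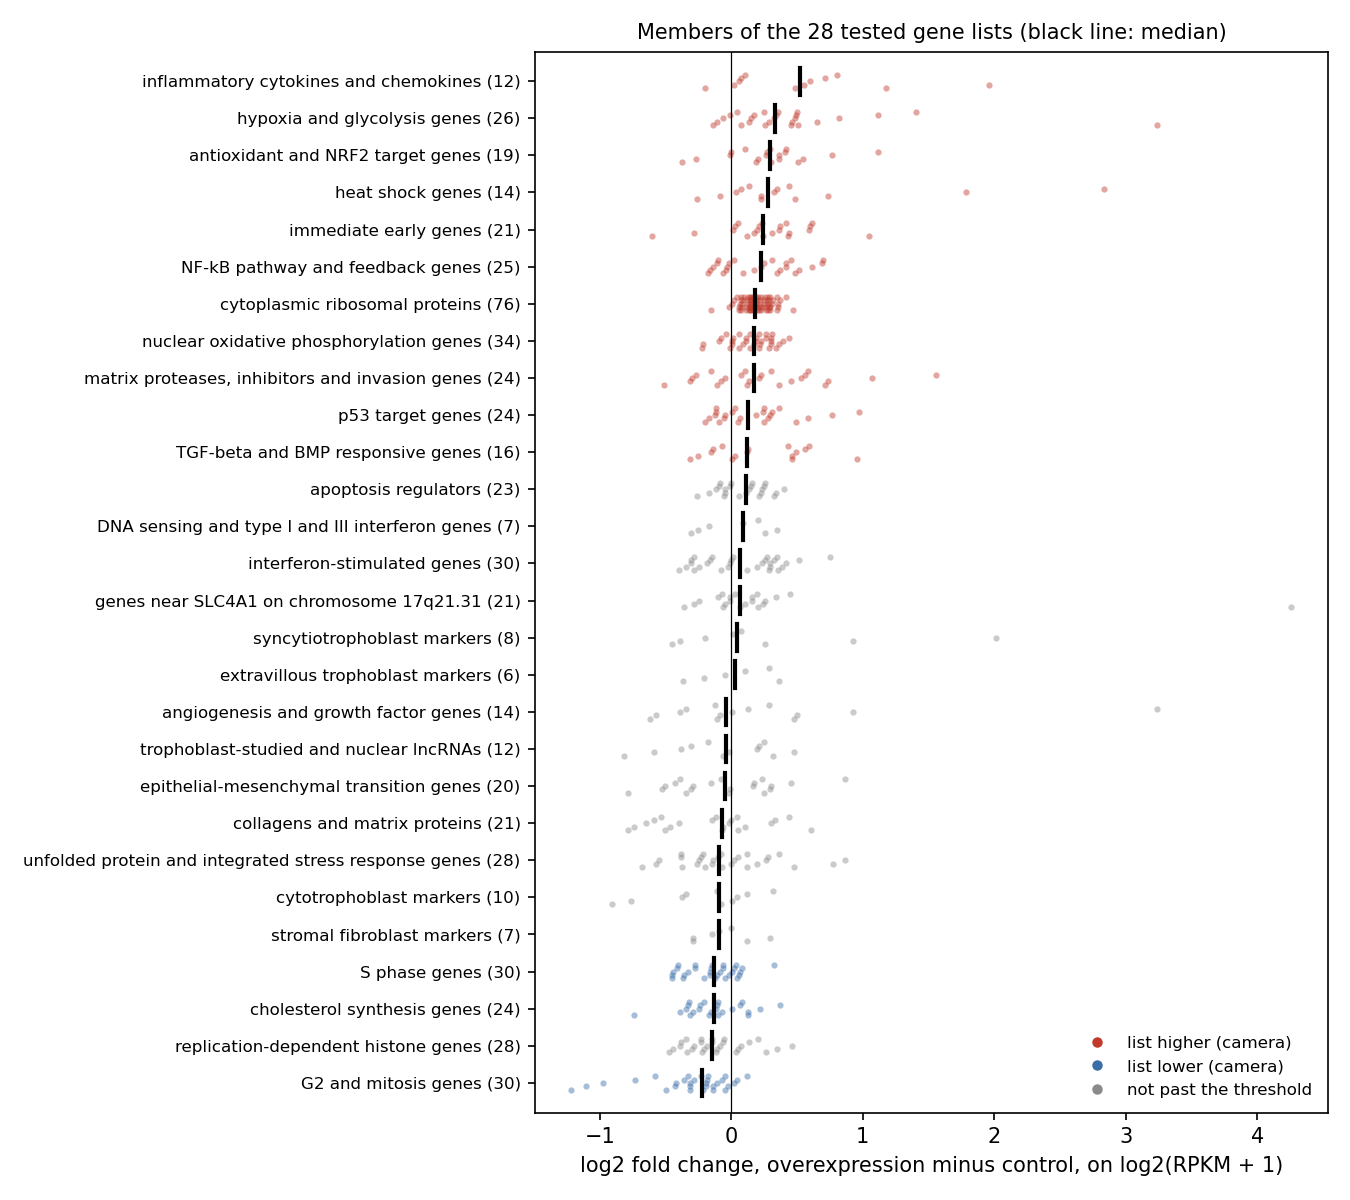
Log2 fold change (overexpression minus control, x axis) of every member of the 28 tested gene lists (y axis, number of tested members in parentheses), with black lines for list medians. Points are genes, in red for the 11 lists that were higher in camera, in blue for the 3 that were lower and in grey for the 14 that did not pass.

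None of the 3 lists of trophoblast markers passed in camera, and for cytotrophoblast markers this depended on the setting. Of 15 cytotrophoblast, 24 syncytiotrophoblast and 19 extravillous markers fixed, 10, 8 and 6 had a mean of at least 1 RPKM and were tested. Of 10 cytotrophoblast markers 1 fell (TFAP2A) and 2 did when adjusted over the list alone, adding PEG10, a retrotransposon-derived imprinted gene (18.8 ± 3.94 to 9.54 ± 2.37 RPKM). Camera gave this list an adjusted p of 0.0596, with 0.0494 without control replicate 1 and 0.0234 without overexpression replicate 3. It was 0.0169 with GC and length trends removed and 0.0178 with fry, lower in each. Of 8 syncytiotrophoblast markers 1 rose (KISS1), and adjusted over the list alone 2 rose (KISS1 and PGF, the placental growth factor gene) and 1 fell (PSG1), with a list adjusted p of 0.321, and 0.0118 with fry. None of 6 extravillous trophoblast markers passed either way (adjusted p = 0.956), and PLAC8 had the smallest p among them (5.41 ± 0.381 and 3.99 ± 0.353 RPKM, adjusted p = 0.355).

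No member of the fixed interferon and apoptosis lists passed the threshold. Of 30 interferon-stimulated genes and 7 genes of DNA sensing and interferons, fixed with the plasmid transfection in mind, none passed over all genes or adjusted over the list alone (list adjusted p = 0.152 and 0.67). The interferon-stimulated list had 0.0170 with fry. ISG20, an exonuclease gene, was at 3.01 ± 0.771 and 5.70 ± 0.594 RPKM (0.75 ± 0.17, adjusted p = 0.213), and TMEM173, which encodes the STING adaptor, at 13.6 ± 0.844 and 17.6 ± 1.11 RPKM (adjusted p = 0.338). Of 23 apoptosis regulators none passed either way (list adjusted p = 0.136), with BAK1 at 33.0 ± 4.56 and 43.98 ± 7.57 RPKM (adjusted p = 0.393). The apoptosis list was higher with GC and length trends removed (0.0169) and with fry (0.0296). Of 28 genes of the unfolded protein and integrated stress responses 0 passed, and CEBPB and PPP1R15A rose when adjusted over the list alone (list adjusted p = 0.67). CEBPB, a transcription factor gene, was at 143.9 ± 20.4 and 263.9 ± 47.5 RPKM (0.86 ± 0.17, adjusted p = 0.143), and passed with GC and length trends removed (0.0348) and without control replicate 1 and overexpression replicate 3 together (0.0457).

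Matrix and other lists did not pass in camera, some of them depending on the setting. Of 21 collagen and matrix protein genes 0 passed, and adjusted over the list alone LAMB3 and COL16A1 rose and 5 fell, led by COL5A2 (63.1 ± 6.31 and 39.9 ± 3.29 RPKM, -0.65 ± 0.12, adjusted p = 0.142 over all genes, and 0.0425 without control replicate 1 and overexpression replicate 3 together). The list had an adjusted p of 0.0715, and 0.00638 without control replicate 1, 0.0113 without overexpression replicate 3 and 0.00342 without both. Of 20 genes of the epithelial-mesenchymal transition 0 passed, and adjusted over the list alone SNAI1 rose and FN1 and CLDN1 fell (list adjusted p = 0.449), with the fibronectin gene FN1 at 36.2 ± 6.55 and 20.6 ± 3.35 RPKM (adjusted p = 0.200). Of 14 angiogenesis and growth factor genes 1 rose (ANGPTL4), and adjusted over the list alone 4 rose (ANGPTL4, PGF, VEGFA and HBEGF). Its median was -0.04 and its mean 0.24, and camera gave it an adjusted p of 0.197, in the direction of the mean, and fry 0.0170. Of 28 replication-dependent histone genes none passed (list adjusted p = 0.163, and 1.6e-04 without overexpression replicate 3, 0.00579 without control replicate 1 as well, and 0.0161 with GC and length trends removed), with HIST1H2BK at 34.8 ± 1.30 and 44.7 ± 4.19 RPKM. Of 7 stromal fibroblast markers none passed (list adjusted p = 0.422), with PDGFRB at 5.79 ± 0.481 and 4.56 ± 0.258 RPKM. Of 12 lncRNA genes none passed (list adjusted p = 0.852), and adjusted over the list alone MIR503HG fell (7.25 ± 1.3 to 3.69 ± 0.764 RPKM, -0.82 ± 0.18, adjusted p = 0.200 over all genes, and 0.0348 with GC and length trends removed).

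Of markers of other cell types, EGFL7 of the endothelial list was at 16.2 ± 2.81 and 20.4 ± 2.89 RPKM (adjusted p = 0.456), and CD68 of the leukocyte list at 83.0 ± 13 and 91.9 ± 6.08 RPKM (adjusted p = 0.643).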

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

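Added after the data were seen were the median-of-ratios scaling, the removal of GC and length trends, the fit without control replicate 1 and overexpression replicate 3 together, and the fit on protein-coding genes. SLC4A1 and CXCL8 kept their direction and passed the threshold in all 15 alternatives, with adjusted p between 3.5e-10 and 0.00296 for SLC4A1 and between 3.4e-07 and 0.0143 for CXCL8. Of the 19 named genes past the threshold, 6 passed in every alternative that tested them. Values of the other named genes fell out of the threshold 70 times and came within it 26 times among 604 comparisons, and no called gene changed sign. Leaving out a library gave 7 to 34 changed genes, 7 to 27 higher, 0 to 7 lower and 7 to 25 changed by at least 1 on the log2 scale. With limma-voom 0 genes were lower and 20 were higher. Without the filter 12 genes changed, 9 higher, and 9 by at least 1, among 28526 tested instead of 14067. With GC and length trends removed 117 genes changed, 82 higher and 35 lower, and 27 of the 27 called genes with a GC value kept their call. Without control replicate 1 and overexpression replicate 3 together 419 changed, 359 higher, 60 lower and 50 by at least 1. All 28 called genes kept their call, with the spread taken from 2 libraries per group. The libraries left out were chosen as the ends of the first component, so this spread can be too small. The cause of these differences was not tested, except that fewer libraries or more genes tested change the counts by construction.

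For gene lists, an estimated correlation left 0 of the 14 calls, with a lowest adjusted p of 0.227, and fry called 17 lists, 11 of them among the 14. The other alternatives called 12 to 17 lists, and 12 of the 14 lists passed whichever library was left out. Raising the filter to 5 RPKM changed the share of the first component from 61.4% to 63.9%.

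With the replicate number of the titles as a block, 312 genes changed, 179 higher, 133 lower and 45 by at least 1, and 28 of the 28 called genes kept their call. Of the named genes, 11 came within the threshold, namely TRND, GADD45A, CEBPB, GDF15, MIR503HG, SCD, FN1, COL5A2, KIF20A, ISG20 and TNFAIP3. Whether the numbers pair the libraries stays open. Deviations of libraries with the same number from their group means correlated at 0.637, -0.238 and 0.429. Control replicates 1 and 3 correlated best with the overexpression library of their own number. The deviations within a group depend on each other, so these correlations cannot exclude a pairing. Control replicate 2 correlated best with overexpression replicate 3 (0.690), so not every library correlated best with its own number. The block raised the list of cytotrophoblast markers past the threshold (0.0481) and changed no other list call.

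The planned DESeq2 test, the edgeR test with RLE factors and the edgeR test without a composition factor were not run, since the table holds RPKM and the fallback was used. Count tests on the reads computed from the RPKM steps would have been possible, and of these only limma-voom was run. Depth limits low genes, since TNF at 0 reads allows levels of up to 0.0606 to 0.0711 RPKM.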

Other observations

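The tests of other splits of the libraries, of the genes around SLC4A1 and of culture conditions were chosen only after the result was seen, as were the genes named in the next paragraph, all fits with GC and length trends removed, and the fit without control replicate 1 and overexpression replicate 3.

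Some of the genes changed were members of no fixed list. The metallothionein genes MT2A and MT1X, which bind zinc and copper, rose from 258.4 ± 50.7 to 663.3 ± 46.6 RPKM and from 4.98 ± 0.525 to 15.4 ± 0.306 RPKM (SD, n = 3 and 3; adjusted p = 0.0208 and 0.0037, limma). The transcript ENSG00000259827.1 overlaps MT1X on the same strand and rose with it. PLIN2, the gene of a lipid droplet coat protein, rose from 54.4 ± 5.07 to 147.4 ± 17.8 RPKM (adjusted p = 0.00665). FAM83A, MYEOV, TM4SF1 and the lncRNA LINC00942 rose too, as did MIR3189, whose record lies within GDF15 on the same strand. With GC and length trends removed, the zinc exporter gene SLC30A1 (11.6 ± 1.34 to 18.2 ± 1.46 RPKM, adjusted p = 0.0171) and G0S2, an inhibitor gene of triglyceride breakdown (149.4 ± 23.4 to 265.7 ± 26.7 RPKM, adjusted p = 0.0108), rose. In that fit ESM1, the gene of a secreted endothelial proteoglycan, was called higher (37.9 ± 9.16 to 78.2 ± 7.29 RPKM, adjusted p = 0.00463). SFRP1, a secreted WNT antagonist gene, was called lower (232.3 ± 20.8 to 139.7 ± 19.6 RPKM, adjusted p = 0.0328). SLC30A1, G0S2, ESM1 and SFRP1 did not pass in the main fit and were picked from the 117 genes called with trends removed. Their RPKM values are the deposited ones, from which no trend was removed. On the simulated data, 13 of 175 calls of the fit with trends removed fell on unchanged genes, against 4 of 114 in the main fit. The simulated trend was of the kind that the fit removes, so the rates in the real data can differ.

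SLC4A1 was near 0 in controls and high in all 3 overexpression libraries. An activation of the whole neighbourhood is argued against by the median log2 change of 0.046 (standard error 0.0585) in 20 neighbours, none of them past the threshold. An erythroid-like programme is argued against by the other erythroid markers, since 0 of 13 exceeded 1 RPKM on average with overexpression and the highest was 0.12. Transcripts of the plasmid that share sequence with the SLC4A1 record cannot be told apart from transcripts of the endogenous gene, because the table gives 1 value per gene and no position of the 2124 or more reads per library. That the plasmid carries sequence counted under SLC4A1 is a candidate explanation and stays untested, as does a biological effect of the lncRNA on the gene.

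The 28 called genes are 1 of 10 ways to split the 6 libraries into 3 and 3, so the share of splits with as many genes cannot go below 0.1; the real split gave 28 genes and the highest of the others 0. With the trend with GC content and length removed, 27 of 27 called genes with a GC value kept an adjusted p of at most 0.05 in limma. The genes had been called in the same libraries for large changes. The removal also lowered the error of genes such as KRT34 (from 0.142 to 0.0647), though not that of CXCL8 (0.131 and 0.132). Keeping the call was therefore likely either way, and it does not decide what part such a trend played. Without the 2 libraries at the ends of the first component, 28 of 28 called genes kept at least 0.67 times their fold change. This cannot decide whether those libraries were the cause. The genes were called with both included, at changes so large against their errors that little room was left to fall below that limit. A difference in culture conditions between the dishes, such as density or oxygen, cannot be told apart from the lncRNA for genes such as those of hypoxia, whose list had a mean log2 change of 0.47, because the design has 1 plasmid per group and no other control. The lncRNA itself stays among the open explanations.

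Control replicate 1 and overexpression replicate 3 lay at opposite ends of the first component, which does not follow the groups. GC content and gene length explained 57.6% of the variance of the gene loadings of that component, in line with a technical difference between the libraries. The G2 and mitosis genes of control replicate 1 lay above the other controls by a median of 0.31, at percentile 99.1 of 10000 random lists matched on GC content and length. The random lists held genes drawn singly, and genes of cell division can vary together, so the percentile can overstate the difference. More dividing cells in that library may also play a part, which stays open. The tests do not rank the explanations, and part of the lower G2 and mitosis list with overexpression may belong to this difference.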
